A study of Mus musculus with 18 samples.

How the data were processed

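The series holds total RNA of 18 mice in 3 groups: 5 controls, 5 CD4Cre-Ctnnbex3 mice before T-cell transformation and 8 mice of that genotype with lymphomas. Thymocytes or tumour masses were collected, and per the labels' protocols RNA was extracted with TRIZOL and an RNeasy column, turned into biotin-labelled cRNA and hybridized to Affymetrix mouse genome arrays, 1 array per mouse. Groups and mouse numbers were taken from the sample labels, and the design text says that the mice were independent. The control group carries 2 descriptions: the design text names LckCre mice and the sample labels name wild type. Which of them is right was not settled, and the group is called control.

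The deposited intensity values are linear probe-set signals that the authors made with dChip, per the series design text. The version of dChip, its expression model and its scaling between arrays are not given in the sources used here. The table has 45101 probe sets, of which 64 are array controls, and no detection calls. Of 811818 values 9775 (1.20%) were blank, on 17 of the arrays. The array of control 1 had no blanks and held 605 of the 606 negative values, the lowest of which was -5436. Blank and low values were set to a floor at the 20th percentile of all values, an intensity of 53.5, and log2 was taken, so that the floor lies at 5.74. Values at the floor have no order, and a change against a group with 3 or more of 5 or 4 or more of 8 mice at the floor is given as at least that size. With fewer mice at the floor the fold is printed as measured and understates the change. Array medians differed by 0.41 on the log2 scale, less than the limit of 0.5 set for rescaling, so the deposited scaling was kept. The 3' to 5' log2 difference lay between -0.27 and -0.00 for Gapdh and between 0.05 and 0.26 for Actb, and arrays correlated with each other at r of 0.734 to 0.983.

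Probe sets were named through the platform annotation, in which 34958 have 1 gene symbol, 932 several and 9160 none, and those with several or none were not used. Each of 18194 genes was represented by the probe set with the highest mean over the 18 arrays, and 14025 genes whose signal was above the 40th percentile (an intensity of 109) on at least 5 arrays were tested. Other probe sets of a gene can disagree with the one used, as they did for Axin2 and Ctnnb1.

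Each of the 3 comparisons was fitted with limma 3.58.1 in R 4.3.3 on its 2 groups alone, with an intensity trend in the empirical Bayes step and Benjamini-Hochberg adjustment over all genes tested. Genes with an adjusted p under 0.05 are said to rise or fall. Each adjusted p of a single gene is limma's. Gene lists were tested with limma's camera, two-sided, with a preset correlation of 0.01 and adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run as alternatives, and no list was called in any comparison with an estimated correlation. The 26 lists covered Wnt/beta-catenin targets, Myc-linked ribosome biogenesis, DNA replication, mitosis, Notch pathway, double-negative, double-positive and single-positive thymocyte stages, T-cell receptor signalling, p53 targets, BCL2 family and caspases, DNA repair, T-cell leukaemia genes, glycolysis, interferon response, MHC, immediate-early genes, sex-linked genes, and markers of B cells, myeloid cells, granulocytes, thymic epithelium, stroma and endothelium, erythroid cells, NK and gamma-delta T cells and adipose tissue. The adipose and sex-linked lists had 4 measured members each, under the minimum of 5, and were counted without a test. The lists share 14 genes.

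The groups, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule names, per comparison, the 10 largest rises and the 10 largest falls among genes that passed and whose values did not overlap between the groups. It adds Ctnnb1, Axin2 and up to 6 members per list with the smallest adjusted p, a member shown as not passing, and leukaemia or Wnt genes in which a single tumour lies apart by Dixon's test. Genes named outside the rule are said to be so. The overlap of both comparisons with control was set beside independent lists, 20 simulations of unchanged groups and split controls, and, after the data were seen, beside simulated lists of the same sizes. The spread within groups was compared by exact permutation tests, two-sided. The same code was tested on simulated data with known changes, with 1 simulation per comparison. Changes were planted only in genes with a mean well above the floor, and the noise of each gene was drawn on its own. The shares recovered thus do not cover genes near the floor, and no share here includes deviations that mice have in common. For mice before transformation against control it recovered 40.3% of 67 genes changed by 0.5 on the log2 scale, 92.5% of 67 changed by 1 and 100% of 66 changed by 2, with 8.02% false calls. For lymphomas against mice before transformation these shares were 29.9%, 83.6% and 98.5%, with 4.32% false, and for lymphomas against controls 34.3%, 92.5% and 97.0%, with 5.23% false.

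Alternatives changed the scaling, the floor, the filter, the probe set per gene, the arrays in the fit, the spread model and the set test, added the mouse number as a block, and left out each mouse in turn. Chosen after the data were seen were blanks kept missing, fits within the mice numbered 1 and 2 or 3 and up, that set as a block, sex from Xist and Y-linked signals as a covariate, male mice alone, and the settings added for the overlap, the spread and the targeted gene. In lymphomas against mice before transformation, where the latter were all male by these signals, the fit with sex rests on the single male tumour. Among mice 1 and 2 controls and lymphomas gave female signals and mice before transformation male ones. Sex thus goes with group in both fits of that set that use mice before transformation. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.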

Results

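RNA from thymocytes or tumour masses of 18 mice, independent per the design text, was measured on Affymetrix mouse expression arrays, with 1 array per mouse. The mice fell into 3 groups. The first held 5 control mice, which the design text describes as LckCre animals and the sample labels as wild type. The second held 5 CD4Cre-Ctnnbex3 mice sampled before transformation, and the third held 8 CD4Cre-Ctnnbex3 mice with lymphoma. Ctnnb1 encodes beta-catenin, the transcriptional effector of canonical Wnt signalling. In this model Cre expressed from Cd4 regulatory sequences alters the gene in thymocytes so that the protein escapes degradation. The median probe-set signal lay between 125 and 166 on the 18 arrays, and the precision of each comparison was limited by the number of mice. The lymphomas stood apart from all other arrays on the first principal component, which held 45.5% of the variance, with scores of 22.4 to 59.5 against -42.9 to -20.1 in the other mice. On the second component (14.1% of the variance) lymphomas 1 and 2 scored -48.9 and -44.0 and the other lymphomas 6.57 to 18.5. Before transformation 1 and 2 scored -11.4 and -26.2 there and the rest of that group 12.6 to 22.7, while controls ran from -17.1 to 12.8. On the third component (10.3% of the variance) controls scored 20.1 to 25.3 and mice before transformation -29.5 to -13.8.

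**Figure D1:**
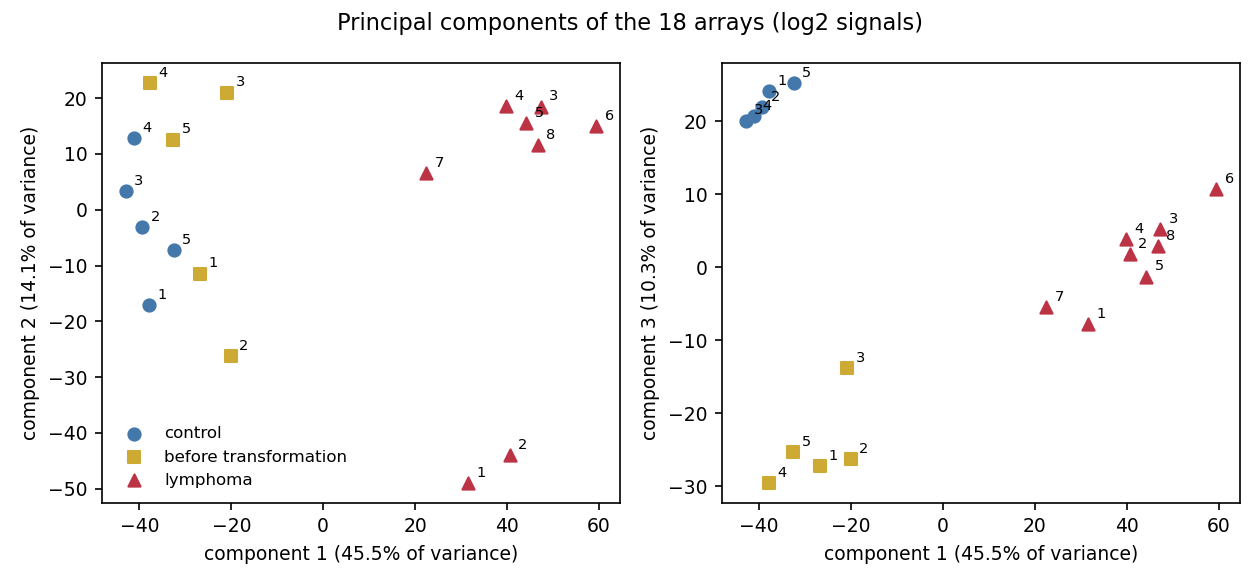
Scores of the 18 arrays on principal components 1 and 2 (left) and 1 and 3 (right), without units, with each point labelled by its mouse number. Lymphomas score 22.4 or more on component 1, and controls score 20.1 or more on component 3.

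Xist, which is transcribed from the inactive X chromosome, and the Y-linked gene Eif2s3y gave female signals in controls 1 and 2 and in 6 lymphomas. Male signals were seen in the other 3 controls, in all 5 mice before transformation and in lymphoma 3. Lymphoma 4 gave both, with a Xist signal of 1110 and an Eif2s3y signal of 313. Whether this sample holds RNA of more than 1 mouse was not tested, and it was kept as 1 mouse in the main fits. Before transformation 1 and 2 and lymphomas 1 and 2 also deviated from their group means together (correlation across genes of 0.170 to 0.408), as did control 1 with these 4 (0.272 to 0.388) but not control 2 (-0.041 to 0.084). Over all 6 mice numbered 1 and 2 the mean between groups was 0.218, so counts within each set of mouse numbers are given beside the pooled ones. The mean log2 signal of the bacterial spike-in controls, which hold no mouse RNA, went with group: it lay at 9.95 to 10.53 in the lymphomas and 10.77 to 11.24 in the other mice among those numbered 3 and up, and at 10.64 to 10.68 and 10.74 to 10.80 among those numbered 1 and 2.

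The first question was whether the altered allele and a known readout of it could be seen in each group. Ctnnb1 had a mean log2 signal of 11.86 ± 0.12 (SD, n = 5) in controls, 12.12 ± 0.13 (n = 5) before transformation and 12.06 ± 0.31 (n = 8) in lymphomas. The difference before transformation was 0.25 ± 0.08 (SE) with a limma adjusted p of 0.0738, and it passed with the mouse-number set as a block (0.0281) and without before transformation 3 (0.0193), where the range over the alternatives was 0.0193 to 0.421. That of lymphomas from control was 0.20 ± 0.14 (limma adjusted p = 0.270). It was 0.35 after quantile normalization (0.0165) and 0.66 with another probe set (0.00675), and both of these passed, while the highest adjusted p over the alternatives was 0.621. A signal for the whole transcript does not measure the loss of 1 exon, so Ctnnb1 does not check the labels. Axin2, a feedback inhibitor and widely used transcriptional target of beta-catenin, rose by 1.46 ± 0.14 on the log2 scale before transformation (2.75-fold, limma adjusted p = 2.85e-05). It rose further by 0.88 ± 0.18 in lymphomas (limma adjusted p = 0.00195), to 5.04-fold above control. Every mouse of both CD4Cre-Ctnnbex3 groups lay above every control for Axin2. With the second Axin2 probe set, at the floor in all 5 controls, the log2 difference before transformation was at least 1.0 and did not pass (limma adjusted p = 0.0512).

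Thymocytes before transformation were compared with control thymocytes to describe what preceded the tumours. The largest rises were in Cadm4, a cell adhesion molecule, by 5.73 ± 0.19 on the log2 scale (53-fold, n = 5 per group), and in Cecr2, a bromodomain protein of chromatin remodelling complexes, by 5.51 ± 0.15. Slc1a4, a neutral amino acid transporter, and Wwc1, a scaffold protein of the Hippo pathway, were at the floor in all controls and at least 29.0-fold and at least 28.1-fold higher before transformation. Cpeb1, which controls translation through the poly(A) tail and was at the floor in 3 of 5 controls, rose at least 26.9-fold, and Gadd45g, a stress-response gene, was at least 24.9-fold higher. Il12rb2, a chain of the interleukin 12 receptor, rose 15.9-fold, Tasp1 15.3-fold and Gpr25 13.7-fold, and Prkaa2, a catalytic subunit of AMP-activated kinase, was at least 14.4-fold higher. The largest falls were in Dhrs3, a retinaldehyde reductase (13.2-fold lower), Ly6d, a surface protein of lymphoid cells (12.1-fold), and Id3, an inhibitor of E-protein transcription factors (9.27-fold). Ccr7, the chemokine receptor of thymocytes entering the medulla, was at least 8.84-fold lower, with 3 of 5 mice before transformation at the floor. Tesc and Scn4b reached the floor in all 5 mice before transformation and were at least 8.23-fold and at least 6.67-fold lower, while Tdrd5, at the floor in 3 of them, was at least 11-fold lower.

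Of 14025 genes tested, 1480 passed an adjusted p of 0.05 in limma, 612 higher and 868 lower before transformation. With an absolute log2 change of at least 1 these were 199 and 181. The values of 1481 genes did not overlap between the groups, or 10.6% of those tested, where chance gives 0.794%. Within the mice numbered 1 and 2 the count of passing genes was 1068, and within those numbered 3 and up it was 1271. In the first of these fits controls 1 and 2 gave female signals and before transformation 1 and 2 male ones, so sex goes with group there. Male mice alone gave 916 genes, and a single fit of all 3 groups with 1 estimate of the spread gave 818.

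The list of positive selection and single-positive genes fell: 16 of 28 measured members fell and 2 rose (adjusted over the list alone, 17 and 2), with a camera adjusted p of 2.01e-06. This call was lost with an estimated correlation (adjusted p = 0.726 with an estimated correlation). Besides Ccr7, the Schlafen gene Slfn1, at the floor in 3 of 5 mice before transformation, was at least 6.39-fold lower, its relative Slfn2 fell by 2.03 ± 0.22, S1pr1, the receptor needed for exit from the thymus, fell by 1.34 ± 0.20, and the surface receptor Cd6 fell by 0.82 ± 0.08. The 2 members that rose, named after their values were seen, were Gata3, required for CD4 T cells, by 0.39 ± 0.11 and Tox by 0.60 ± 0.11. Among 13 Notch pathway genes 5 fell and none rose (7 and 0 adjusted over the list alone; camera adjusted p = 0.000421, and adjusted p = 0.650 with an estimated correlation). Notch1 fell by 2.03 ± 0.11, the glycosyltransferase Lfng fell by 2.20 ± 0.25, and Ptcra, the invariant chain of the pre-T-cell receptor, fell by 1.78 ± 0.11, whereas Hes1, a target of Notch, differed by -0.05 ± 0.25 (limma adjusted p = 0.957).

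Replication genes of the G1/S list fell in 5 of 24 members and rose in 1 (10 and 1 adjusted over the list alone), with a camera adjusted p of 2.57e-05 (adjusted p = 0.726 with an estimated correlation). The licensing factor Cdt1 fell by 0.80 ± 0.15 and Rrm2, a subunit of ribonucleotide reductase, fell by 0.52 ± 0.11. No single member passed in limma in the lists of mitosis (24 measured, camera adjusted p = 0.00571) or Myc-linked ribosome biogenesis (25 measured, 0.00975), whose medians were -0.30 and -0.21. DNA repair had 1 member up and 1 down of 22 (5 down adjusted over the list alone), with a median of -0.35 and a camera adjusted p of 0.00850. With an estimated correlation these 3 lists were not called (adjusted p = 0.877 for each), nor in male mice alone (0.0771 to 0.180) or with sex as a covariate (0.0716 to 0.179). Controls 1 and 2 were the only mice with female signals here, so both sex settings cannot tell sex from mouse number among controls. In mice 1 and 2 alone the mitosis list turned to the other direction (0.473) and DNA repair was not called (0.454). Without before transformation 4 none of the 3 was called (0.0886 for mitosis, 0.0844 for ribosome biogenesis and 0.0573 for DNA repair), which left 5 lists in place of 8. Mitosis and DNA repair were also lost without before transformation 3 (0.0520 and 0.0502), and ribosome biogenesis without before transformation 5 (0.0711) or control 1 (0.0642). Over all alternatives with the preset correlation the ranges were 1.86e-09 to 0.473 for mitosis, 0.000316 to 0.180 for ribosome biogenesis and 0.000177 to 0.454 for DNA repair.

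Interferon response genes fell in 6 of 19 members (12 adjusted over the list alone, with 1 up), with a camera adjusted p of 6.47e-05 (adjusted p = 0.650 with an estimated correlation). The guanylate-binding protein Gbp2 fell by 0.81 ± 0.17 and the GTPase Irgm1 fell by 0.98 ± 0.17. Gbp2 did not pass with all 3 groups in 1 fit (limma adjusted p = 0.520, lowest over the alternatives 0.000887). Irgm1 did not pass in mice 3 and up alone (0.0783, lowest 0.000658). Granulocyte markers fell alongside: 6 of 10 members, also 6 adjusted over the list alone, with a camera adjusted p of 0.000367 (adjusted p = 0.650 with an estimated correlation). S100a9 and S100a8, the abundant calcium-binding proteins of neutrophils, fell by 3.51 ± 0.56 and fell by 3.27 ± 0.58. The remaining 16 tested lists were not called (adjusted p of 0.0865 to 0.924). In settings chosen after the data were seen some of them were: in mice 3 and up alone thymic epithelium and myeloid markers and MHC genes were higher (0.000668, 0.00627 and 0.0149), as was thymic epithelium in male mice alone (0.00436), and in mice 1 and 2 alone B-cell markers were lower (0.00669). Over the alternatives with the preset correlation the highest adjusted p of these 4 lists was 0.554, 0.949, 0.962 and 0.514, and the lowest for B-cell markers was 0.000364. Before transformation 3 lay above the other 4 mice of its group for 9 of 10 B-cell markers, so the B-cell list depends on this mouse. Of the Wnt/beta-catenin targets 5 of 22 rose and 5 fell (6 and 5 adjusted over the list alone; camera adjusted p = 0.211). The adhesion receptor Cd44 rose by 3.49 ± 0.21 and Nkd1, an inhibitor of Dishevelled, by 0.61 ± 0.11, while Id2, an inhibitor of E proteins, fell by 1.44 ± 0.25 and the transcription factor Lef1 fell by 0.53 ± 0.09. Ccnd2, a D-type cyclin, and Myc, both singled out after their values were seen, fell by 2.30 ± 0.47 and fell by 1.08 ± 0.29. Of 18 myeloid markers 1, the integrin Itgam, rose by 3.73 ± 0.23, and none fell.

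Lymphomas were next compared with thymocytes before transformation, to follow what changed as tumours formed. The largest rises were in Pou2af1, a lymphoid transcriptional coactivator, by 4.28 ± 0.56 (19.4-fold, 8 lymphomas against 5 mice), and in Stra6, the receptor for retinol-binding protein, which was at the floor before transformation and at least 18-fold higher. Ak5, an adenylate kinase, rose 13.9-fold, Igfbp7 13.2-fold, the proteoglycan Spock2 12.8-fold, the small GTPase Rhob 12-fold and the acute-phase gene Saa3 10.5-fold. Esx1 and Efhd1 were at the floor before transformation and at least 13.5-fold and at least 10.9-fold higher. The largest falls were in Ptprf, a receptor tyrosine phosphatase, 16.5-fold, and in Arpp21, a marker of double-positive thymocytes, 13.1-fold. Rag2, at the floor in 5 of 8 lymphomas, and Dntt, which act in antigen-receptor gene rearrangement, were at least 11.2-fold and 11.1-fold lower, and Nebl, F13a1 and Ramp1 were 12.3-fold, 12-fold and 11.2-fold lower. Myc rose by 3.02 ± 0.26, or 8.11-fold, to 3.83-fold above control.

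Of 14025 genes, 4819 passed, with 2246 higher and 2573 lower in lymphomas, and at an absolute log2 change of at least 1 these were 554 and 652. After quantile normalization the split was 3178 higher and 2218 lower, and after centring each array on its median it was 2745 and 1945. The values of 2176 genes (15.5%) did not overlap, where chance gives 0.155%. The mice numbered 1 and 2 alone gave 2577 passing genes, 2008 of them among the 4819 in the same direction, and those numbered 3 and up, whose spike-ins differed more between the groups, gave 5840 (4173). In the first of these fits lymphomas 1 and 2 gave female signals and before transformation 1 and 2 male ones, so sex goes with group there. All 5 mice before transformation gave male signals, and lymphoma 3 was the single tumour with male signals alone. With sex as a covariate and without lymphoma 4, a setting chosen after the data were seen, 570 genes passed, 221 higher and 349 lower, and 536 of the 4819 genes passed in the same direction. That difference between the groups rests on lymphoma 3, so it does not tell how much of the pooled count goes with sex.

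The list of Myc-linked ribosome biogenesis rose, with 22 of 25 members up and 1 down (the same counts adjusted over the list alone) and a camera adjusted p of 8.83e-15 (adjusted p = 0.146 with an estimated correlation). Srm, the spermidine synthase, rose by 1.90 ± 0.19, Cad, which starts pyrimidine synthesis, by 1.79 ± 0.15, Dkc1, a component of nucleolar ribonucleoproteins, by 1.58 ± 0.16 and Rrs1, a ribosome assembly factor, by 1.30 ± 0.11. Glycolysis genes rose in 8 of 15 members and fell in 1 (8 and 2 adjusted over the list alone), with a camera adjusted p of 0.00267 (adjusted p = 0.530 with an estimated correlation, and 0.268 with sex as a covariate, the highest over the alternatives with the preset correlation, of which the lowest was 0.000971). Hk2, a hexokinase, rose by 1.65 ± 0.19, the triose phosphate isomerase Tpi1 by 1.56 ± 0.23 and the glucose transporter Slc2a3 by 2.06 ± 0.33, while the member that fell, the hexokinase Hk1 (named after its value was seen), fell by 0.56 ± 0.10. DNA repair genes rose in 9 of 22 members and fell in 1, as they did adjusted over the list alone (camera adjusted p = 0.0112, and adjusted p = 0.530 with an estimated correlation). In mice 1 and 2 alone the DNA repair list was not called (0.0834, the highest over the alternatives with the preset correlation, of which the lowest was 0.00176). Xrcc5, which encodes the Ku80 end-binding protein, rose by 2.23 ± 0.26.

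Genes of the double-positive stage fell in 14 of 18 members and rose in none, as they did adjusted over the list alone (camera adjusted p = 6.63e-08, and adjusted p = 0.146 with an estimated correlation). Besides Arpp21, Rag2 and Dntt, the coreceptor genes Cd4 and Cd8b1 fell by 1.21 ± 0.17 and fell by 1.01 ± 0.11, and Cd1d1, which presents lipids to T cells, fell by 1.21 ± 0.13. T-cell receptor complex and signalling genes fell in 16 of 21 members (17 adjusted over the list alone), with the same camera adjusted p of 6.63e-08 (adjusted p = 0.146 with an estimated correlation). The receptor subunits Cd247 and Cd3e fell by 1.59 ± 0.18 and fell by 1.26 ± 0.13, the kinase Prkcq fell by 1.63 ± 0.20 and the adaptor Lat fell by 0.96 ± 0.08.

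Markers of other cells moved with these groups. Thymocytes or tumour masses were collected, so the material may differ between the groups of mice. Its part in these markers was not tested. Myeloid markers rose in 10 of 18 members and fell in 1 (12 and 2 adjusted over the list alone; camera adjusted p = 0.000560, and adjusted p = 0.530 with an estimated correlation), and the abundant macrophage genes Lyz2 and C1qa rose by 2.80 ± 0.48 and 2.74 ± 0.43. Stroma and endothelium markers rose in 8 of 15 (10 adjusted over the list alone; camera adjusted p = 0.00251, and adjusted p = 0.530 with an estimated correlation), with Bgn, a matrix proteoglycan at the floor in 3 of 5 mice before transformation, at least 8.74-fold higher and the matrix glycoprotein Sparc up by 1.82 ± 0.46. Granulocyte markers rose in 5 of 10, also adjusted over the list alone (camera adjusted p = 0.0477, and adjusted p = 0.530 with an estimated correlation), a call that 19 of 30 alternatives did not keep (0.0181 to 0.315 over those with the preset correlation), among them those without before transformation 1, 2 or 4 or lymphoma 2, 5 or 6 (0.0596 to 0.0733). Thymic epithelium markers fell in 6 of 13 members and rose in 1 (9 and 1 adjusted over the list alone), with a camera adjusted p of 0.00188 (adjusted p = 0.517 with an estimated correlation). Prss16, a protease of the thymic cortex, fell by 2.60 ± 0.20 and the chemokine Ccl25, at the floor in 6 of 8 lymphomas, was at least 3.65-fold lower. In the mice numbered 1 and 2 alone the stroma list had an adjusted p of 0.444 and the thymic epithelium list one of 0.0627, each the highest over the alternatives with the preset correlation, of which the lowest were 0.000109 and 0.000326. The other 15 tested lists were not called (adjusted p of 0.0770 to 0.966), and the Wnt/beta-catenin targets were among them (9 up and 3 down of 22, as adjusted over the list alone; 0.0770). Of these lists DNA replication was called in 8 of 30 alternatives, mitosis in 4, and Wnt/beta-catenin targets and T-cell leukaemia genes in 3 each, and B-cell markers were higher with sex as a covariate (1.27e-05, highest over the alternatives 0.863).

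**Figure D2:**
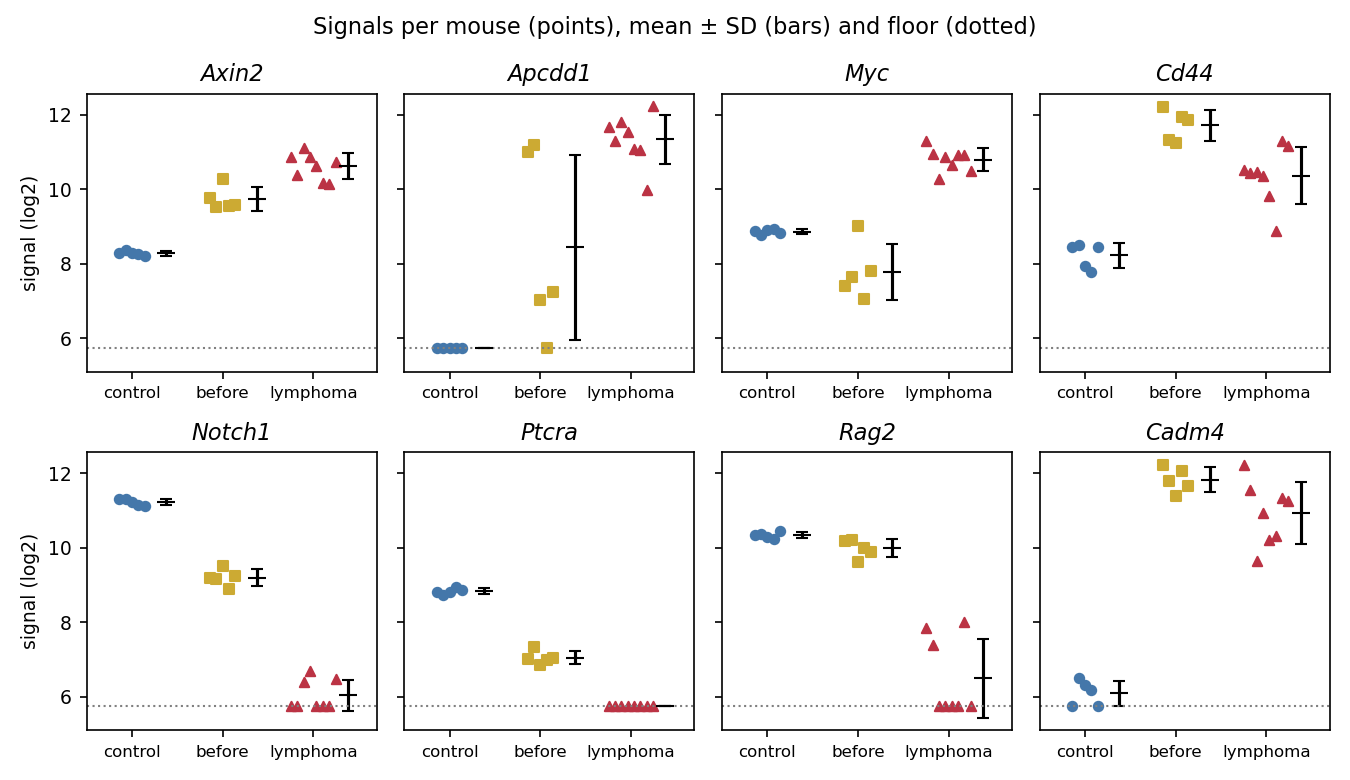
Log2 signal of 8 genes in each of 5 control mice, 5 mice before transformation and 8 lymphomas, with the mean and SD of each group as bars and the floor as a dotted line. Axin2 averages 8.28, 9.74 and 10.61 in the 3 groups, and Notch1 11.22, 9.20 and 6.03.

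The comparison of lymphomas with control thymocytes spans both steps. Apcdd1, an inhibitor and target of Wnt signalling, was at the floor in all 5 controls and at least 48.3-fold higher in the 8 lymphomas, and Wwc1 at least 45.1-fold. Gadd45g was at least 30.4-fold higher, Spock2 rose 29.7-fold, Cadm4 28.7-fold, Igfbp7 24.0-fold, Pou2af1 23.3-fold and Hemgn, a haematopoietic nuclear protein, 20.8-fold. Cpeb1 and Inava, at the floor in 3 and 4 of 5 controls, were at least 21.1-fold and at least 17.9-fold higher. Arpp21 was 41.2-fold lower, Notch1 at least 36.5-fold (with 5 of 8 lymphomas at the floor) and Ramp1 28.7-fold lower. Aqp11 and Dhrs3, also at the floor in 5 lymphomas, were at least 19.7-fold and at least 18.6-fold lower, P2ry10, at the floor in 4, at least 17.4-fold, and Chrna9, at the floor in 7, at least 15.7-fold. Ptprf was 17.5-fold lower, Ly6d 16.3-fold and Cd96 16.1-fold. Ptcra was at the floor in all 8 lymphomas and at least 8.52-fold lower.

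In this comparison 5625 of 14025 genes passed, 2438 higher and 3187 lower, and at an absolute log2 change of at least 1 these were 572 and 872. After quantile normalization the split was 3593 higher and 2551 lower, and after centring on array medians 3026 and 2439. Quantile normalization moved the median change of all genes from -0.03 to 0.08 on the log2 scale. The values of 2833 genes (20.2%) did not overlap, where chance gives 0.155%. The mice numbered 1 and 2 alone gave 3975 passing genes, 2795 of them among the 5625 in the same direction, and those numbered 3 and up, whose spike-ins differed more between the groups, gave 5849 (4722).

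Wnt/beta-catenin targets rose in 10 of 22 members and fell in 5 (11 and 6 adjusted over the list alone), with a camera adjusted p of 0.0101 (adjusted p = 0.135 with an estimated correlation, 0.202 with blank values kept missing and 0.0871 in mice 1 and 2 alone, with a range of 0.00536 to 0.202 over the alternatives with the preset correlation). Wif1, a secreted Wnt inhibitor, was at least 17.4-fold higher, and Nkd1 rose by 1.97 ± 0.22 and Cd44 by 2.14 ± 0.32. Ribosome biogenesis genes rose in 22 of 25 members and fell in 1, as adjusted over the list alone (camera adjusted p = 3.27e-12, and adjusted p = 0.135 with an estimated correlation). Glycolysis genes rose in 8 of 15 and fell in 1 (9 and 2 adjusted over the list alone; camera adjusted p = 0.00486, and adjusted p = 0.491 with an estimated correlation). Of the Notch pathway genes 6 of 13 fell and 1 rose (7 and 1 adjusted over the list alone), but the list was not called (camera adjusted p = 0.0552), although 16 of 30 alternatives did call it (adjusted p of 0.00150 to 0.465 over those with the preset correlation).

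Double-positive genes fell in 15 of 18 members, also adjusted over the list alone (camera adjusted p = 5.78e-07, and adjusted p = 0.135 with an estimated correlation). Single-positive genes fell in 21 of 28 and rose in 2 (23 and 3 adjusted over the list alone; camera adjusted p = 3.60e-06, and adjusted p = 0.410 with an estimated correlation). T-cell receptor genes fell in 16 of 21 (17 down and 1 up adjusted over the list alone; camera adjusted p = 1.70e-06, and adjusted p = 0.186 with an estimated correlation). Interferon response genes fell in 12 of 19 (13 adjusted over the list alone; camera adjusted p = 0.000349, and adjusted p = 0.491 with an estimated correlation), with Usp18, a regulator of the interferon receptor at the floor in 6 of 8 lymphomas, at least 3.44-fold lower and Rtp4 at -1.48 ± 0.14 on the log2 scale. Myeloid markers rose in 14 of 18 and fell in 2, as adjusted over the list alone (camera adjusted p = 0.000349, and adjusted p = 0.491 with an estimated correlation). Stroma and endothelium markers rose in 9 of 15 (10 adjusted over the list alone; camera adjusted p = 0.00127, and adjusted p = 0.491 with an estimated correlation). Thymic epithelium markers fell in 7 of 13, also adjusted over the list alone (camera adjusted p = 0.0247, and adjusted p = 0.491 with an estimated correlation). The thymic epithelium list was not called in the mice numbered 3 and up alone (adjusted p = 0.140), with a stricter filter (0.129) or with array quality weights (0.0659), where the alternatives with the preset correlation ranged from 0.00143 to 0.140, and in those numbered 1 and 2 alone that of the stroma list was 0.164 (range 0.000248 to 0.164). The other 14 tested lists were not called (adjusted p of 0.0552 to 0.702).

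**Figure D3:**
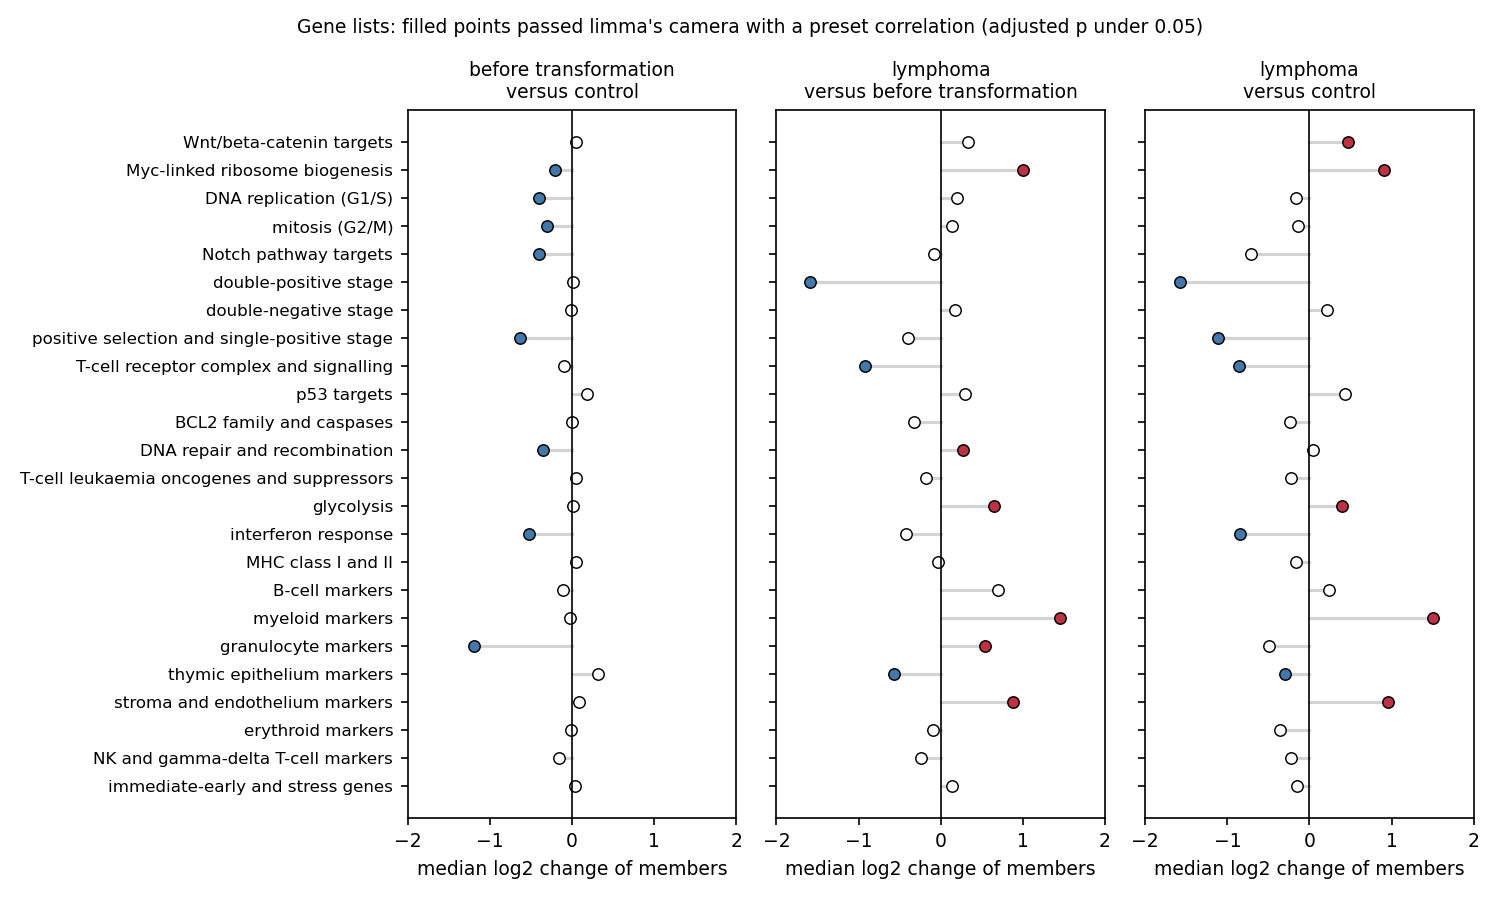
Median log2 change of the measured members of the 24 tested gene lists in the 3 comparisons, with filled points where camera with a preset correlation gave an adjusted p under 0.05. Filled points number 8, 9 and 10 in the 3 comparisons, and none was called with an estimated correlation.

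The changes before transformation were set beside those in lymphomas, both against the same 5 controls. Of the 1480 genes that passed before transformation, 253 were higher and 575 lower in both comparisons, 828 in all, and 110 changed in opposite directions. Independent lists of these sizes would share 106 and 197 genes. Simulated unchanged groups against the same controls gave at most 3 and 2 passing genes and none shared, which says little of lists this long. When as many genes as had passed were therefore taken from 20 such simulations by their p, a test chosen after the result was seen, 269 to 313 were higher and 428 to 474 lower in both, and 72 to 100 opposite. The 253 shared rises lie below these simulated counts and the 575 shared falls above them. With the controls split, so that each comparison had its own, 104 genes were higher and 186 lower in both with controls 1 and 2 for the mice before transformation, where independent lists would share 35.2 and 49.1. The other way round these were 122 and 266, against 35.8 and 59.3. Between the 2 stages, 309 of the 612 genes that were higher before transformation then fell in lymphomas and 53 rose further, among them Axin2 and Nkd1. Of the 868 genes that were lower, 151 then rose, among them Myc and Ccnd2, and 223 fell further, among them Notch1, Ptcra and Arpp21. Both steps share the mice before transformation with opposite sign, which by itself turns genes back. Simulated unchanged groups with lists of these sizes gave 365 to 400 and 447 to 503 genes that turned back, more than the 309 and 151 observed, and 2 to 20 and 13 to 29 that moved further, fewer than the 53 and 223.

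Expression profiles differed more between lymphomas than between thymi. The median of 1 minus the correlation of a mouse with the other mice of its group averaged 0.0836 ± 0.0220 (SD, n = 8) in lymphomas, 0.0549 ± 0.0120 (n = 5) before transformation and 0.0358 ± 0.00228 (n = 5) in controls. Two-sided exact permutation tests gave p = 0.00155 for lymphomas against controls, p = 0.00794 for mice before transformation against controls and p = 0.0241 for lymphomas against mice before transformation. The last of these did not pass without before transformation 5 (exact p = 0.178), lymphoma 1 (0.0821), lymphoma 2 (0.0960) or lymphoma 6 (0.0846), nor with no filter on low signals (0.0513). These distances share arrays within a group and are not fully independent. Among 47 oncogenes and tumour suppressors of T-cell leukaemia and Wnt targets, a single tumour lay apart by Dixon's test for 2, where chance gives about 2.35: for Ikzf1, a lymphoid zinc-finger factor, and the retinoblastoma gene Rb1. Lymphoma 6 was the lowest for both, at 11.37 against 11.71 in the next tumour for Ikzf1 and at 8.14 against 9.22 for Rb1.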

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

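Chosen after the result was seen were the tests of a lower thymocyte share, dilution, sex, lymphoma cells and B cells, the set of mice numbered 1 and 2, the within-set settings and the verdict on hybridization. A mouse whose value lies far from the rest of its group was looked for by Dixon's test in 315 groups of values, those of 104 genes and the distances between profiles in 3 groups. Of these 22 (6.98%) stood out, where chance gives about 1 in 20 groups of normal values without ties. Many groups are tied at the floor: for Chrna9, Inava, Stra6 and Wif1 the value stood out as the only one of its group off the floor. Groups wholly at the floor cannot stand out, so the share does not tell how many of these values need a cause beyond chance. Before transformation 3 had 5 of them: it was the highest of its group for Wif1 (10.52 on the log2 scale), Pou2af1 (9.08) and Srm (9.48), and the lowest for Dntt (12.65) and Cd8b1 (12.71). Before transformation 1 was the highest for Bgn (6.97) and Sparc (8.06), and before transformation 5 for Ccr7 (5.97). Lymphoma 7 was the highest tumour for Arpp21 (8.83), Cdt1 (10.80) and Chrna9 (6.55), and lymphoma 1 for Wwc1 (11.86). Lymphoma 6 was the lowest for Ikzf1 (11.37), Rb1 (8.14) and Tasp1 (5.74), and lymphoma 3, the tumour with male signals alone, for Xist (6.18). Among controls, control 2 was the highest for Cpeb1 (6.06) and Inava (5.79) and control 4 for Stra6 (6.05), while control 3 was the lowest for Lyz2 (9.01) and S1pr1 (7.85) and control 5 for Scn4b (7.73).

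Other splits of the same mice were run for every count, with 100 splits of each comparison, the real one included. For mice before transformation against control 1 split of 100 gave as many genes, the real one (1480). A count as large was thus rare among the splits drawn. The highest other split, which mixed the groups, gave 1378, so the size of the count alone does not mark the real grouping. That other split set before transformation 1 and 2 and controls 1, 2 and 5 against the rest. It held all 4 mice numbered 1 and 2 on 1 side, but the same split with control 3 in place of control 5 gave 2 genes, so it does not follow the mouse numbers alone. With the mouse-number set as a block 1971 genes passed, and within the sets 1068 and 1271, where sex goes with group in the first. For lymphomas against mice before transformation (4819, highest other 241) and against control (5625, highest other 1138) the real split alone, 1 of 100 each, gave as many genes. Every other split drawn gave far fewer. For the number of gene lists chance is not excluded: 30 splits gave at least the 8 lists called before transformation (highest other 13), 30 at least the 9 in lymphomas against mice before transformation (highest 14), and 22 at least the 10 against control (highest 13).

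In lymphomas against mice before transformation T-cell receptor and double-positive genes were lower, and macrophage and stromal genes higher. Thymocytes or tumour masses were collected, and whether this difference in material accounts for the markers of other cells was not tested. A lower share of thymocytes alone would raise markers of every other cell type alike, but the thymic epithelium list had a median of -0.57 while the myeloid list rose (Fisher's exact p = 0.00845 for members up). More macrophages in some tumours than in others would make myeloid markers vary together. Their mean pairwise r over the 8 lymphomas was 0.649, where the highest of 1000 random lists gave 0.264. Random lists do not hold related genes, so this does not single out differing numbers of macrophages. Camera's estimated correlation was higher for MHC, B-cell and mitosis genes (0.881, 0.755 and 0.655) than for myeloid markers (0.567), and lower for the other tested lists. Dilution of the T-cell lineage by other cells as the source of all the falls would let no T-cell gene fall further than the 4 CD3 genes (mean -1.28), yet of the 35 other members of both lists 3 did (Arpp21, Rag2 and Dntt, Arpp21 by -2.43 relative to them) and 10 fell less (exact permutation p adjusted over the members). The falls were thus unequal, but fewer than the 5 members set as the bound fell further and those 3 were among the largest falls, so dilution cannot be told apart from changes within the T-cell lineage.

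Mice numbered 1 and 2 deviated from their group means alike, with a mean r of 0.218 between groups (exact p = 0.000714 over 2800 assignments). Control 2 was the exception (mean r of 0.0138 with the 4 such mice of the other groups, against 0.349 for control 1), and with control 5 in its place the mean r was 0.253. The numbers 1 and 2 were singled out because these mice were seen to deviate together, so that exact p cannot serve as a test of chance. Sex is argued against, because all 5 mice before transformation gave male signals and before transformation 1 and 2 still deviated with lymphomas 1 and 2 at a mean r of 0.290. For a shared hybridization batch, the spike-in controls differed between mice 1 and 2 and the rest by -0.031 on average, with differing directions (-0.13 in controls, -0.29 before transformation and 0.33 in lymphomas), which met the bound set beforehand against a batch. That bound took the higher numbers for 1 batch, which is not known. Their spike-ins went with group (9.95 to 10.53 in the lymphomas, 10.77 to 11.24 in the other mice), which does not tell batches from group. Lymphomas were also lower among mice 1 and 2 (10.64 to 10.68 against 10.74 to 10.80). Spike-ins of the 6 mice numbered 1 and 2 lay within 0.157 (exact p = 0.00107, for a set and a measure picked after the data were seen). The sample order of the series, read after these results, puts these 6 mice together. They follow the other lymphomas and precede the other controls and mice before transformation. The spike-in ranges rise in that order, with some overlap: 9.95 to 10.53, then 10.64 to 10.80, then 10.77 to 11.24. Order and spike-ins both go with a batch shared by the 6 mice, although the order gives no hybridization dates. Control 2 shared the spike-in level of the 6 mice but not the deviation, and 1 mouse excludes nothing. A batch thus cannot be told apart from other shared conditions of mice 1 and 2, such as age or litter, which were not tested. Nor can hybridization be told apart from group in the higher numbers.

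Before transformation 3 held 16 genes more than 2 log2 units above every other mouse before transformation and every control, among them Wif1, Grb10, Adk, Spock2 and Ms4a1, and no other mouse before transformation held any; 10 lay within the range of the lymphomas, 2 below and 4 above it. Lymphoma cells with levels like those of the 8 tumours are argued against as the source of all 16: they do not reach the 4 genes at any share, and at the share that the other 12 need (85.0%), 11 of 12 further genes, high in every lymphoma and low in the other 9 mice, lay below the level needed (exact signed-rank p = 0.000977, genes taken as independent). For 9 of the 16 the share is 60.4% (exact p = 0.0210), but for lymphoma cells as the source of up to 8 it is 43.2% or less (exact p = 0.129), and 8 of the 12 further genes lay above those 9 mice, so that a smaller share cannot be told apart from single genes rising in this mouse. B cells may account for part of the pattern: Ighm was at 11.26 against 8.65 to 9.92 in the other 4 mice, and 9 of 10 B-cell markers lay above them, with Ms4a1 among the 16 genes. Ighm reached 12.27 in a control, and B cells do not cover Wif1, a member of the Wnt target list.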

How the results depend on the processing

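Settings within mouse numbers, with blanks kept missing, with sex, and those leaving out a mouse for the overlap, the spread or the targeted gene were chosen after the data were seen. The number of changed genes stayed within 1.5 times its value in 25 of 28 alternatives for mice before transformation against control, 27 of 30 for lymphomas against mice before transformation and 29 of 30 for lymphomas against control. The exceptions were every probe set tested on its own (3111, 11003 and 12263, over 29947 probe sets), and for single comparisons 4 further settings. These were all 3 groups in 1 fit (818), male mice alone (916) and mice 1 and 2 alone (2577), the last 2 with fewer mice, and sex as a covariate without lymphoma 4 (570). Leaving out lymphoma 4 alone gave 4374, so the fall to 570 goes with the adjustment for sex, which nearly coincides with group. Leaving out 1 mouse gave 1150 to 1642, 3755 to 5187 and 4730 to 6099 genes. No list was called with an estimated correlation (0 in each comparison), fry called 4, 13 and 14, and for mice before transformation against control leaving out 1 mouse gave 5 to 9, the lowest without before transformation 4. Axin2 before transformation had a log2 difference of at least 1.0 with its second probe set (adjusted p = 0.0512). For Ctnnb1 before transformation, leaving out 1 mouse gave 0.21 to 0.31 (adjusted p = 0.0193 without before transformation 3), and the mouse-number set as a block gave 0.25 (0.0281). For Ctnnb1 in lymphomas against control, quantile normalization gave 0.35 (0.0165) and another probe set 0.66 (0.00675). The overlap of both comparisons with control was 446 at an adjusted p of 0.01 and 542 with 1 fit. The spread of lymphomas over mice before transformation was 0.0158 without a filter (exact p = 0.0513) and 0.0174 to 0.0382 without 1 mouse. Directions turned for mitosis before transformation in mice 1 and 2 alone (adjusted p = 0.473), MHC genes before transformation in mice 3 and up (0.0149), the double-negative list in lymphomas against control with fry (0.000395) and Cdc6 in lymphomas against mice before transformation in mice 1 and 2 (-0.22). The cause was not tested. Among named genes that passed (94, 128 and 138), the fewest kept were 59 (all 3 groups in 1 fit), 51 (sex as a covariate; 83 in mice 1 and 2) and 111 (mice 1 and 2), and quantile normalization kept 93, 127 and 133. With the mouse number as a replicate block 1448, 4951 and 4926 genes passed. Pairs of mice with 1 number correlated at -0.143 to 0.382, 0.0904 to 0.408 and -0.0690 to 0.272. Their mean r was 0.126, 0.222 and 0.0834, against 0.114, 0.114 and 0.0793 for other pairs of the same set. In each comparison 2 of 5 mice correlated best with their own number, which neither shows nor excludes pairing with so few pairs. That the mice were independent rests on the design text. Signals at the floor limit what can be said of genes with low expression.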

Other observations

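The tests on chromosome 15, on T-cell receptor variable segments and on the neighbours of Ctnnb1 were chosen after the result was seen. Genes of survival and growth control outside the groups described so far moved in both directions. Among 16 p53 targets 6 rose and 5 fell in lymphomas against mice before transformation (7 and 5 adjusted over the list alone; camera adjusted p = 0.688). Cdkn1a, an inhibitor of cyclin-dependent kinases, rose by 2.10 ± 0.49 on the log2 scale, and the death receptor Fas fell by 3.05 ± 0.40. Before transformation 1 member rose and 1 fell (2 and 1 adjusted over the list alone; 0.206), and against control 8 rose and 6 fell in lymphomas, as adjusted over the list alone (0.447). Of 16 BCL2 family and caspase genes 2 rose and 8 fell (3 and 8 adjusted over the list alone; camera adjusted p = 0.162), among them the proapoptotic Bcl2l11, which fell by 1.81 ± 0.29, and the antiapoptotic Bcl2l1, which fell by 1.49 ± 0.20. That list had 1 up and 3 down before transformation (2 and 3 adjusted over the list alone; 0.924) and 2 up and 7 down in lymphomas against control, as adjusted over the list alone (0.326). Of 25 T-cell leukaemia genes 5 rose and 1 fell before transformation (5 and 2 adjusted over the list alone; 0.125), with the ubiquitin ligase subunit Fbxw7 up by 0.96 ± 0.12. In the lymphomas 2 rose and 6 fell, as adjusted over the list alone (0.156): the T-cell identity factor Bcl11b fell by 1.58 ± 0.20 and Lyl1, a helix-loop-helix oncogene, rose by 0.89 ± 0.18. Against control 4 rose and 9 fell (6 and 9 adjusted over the list alone; 0.697).

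The remaining lists were not called by camera in any comparison, although some alternatives called 1 or more of them, and their results follow in the order before transformation against control, lymphoma against before transformation, and lymphoma against control. Immediate-early genes had 1 up and 4 down of 12, 1 and 3, and none up and 6 down (adjusted p = 0.541, 0.902 and 0.396), and Zfp36, which destabilizes cytokine transcripts, fell by 1.01 ± 0.14 in the first and fell by 0.81 ± 0.16 in the second. Adjusted over the list alone these counts were 2 and 4, 1 and 3, and 3 and 6. Double-negative stage genes had 1 up and 3 down of 14, 3 and 3, and 5 and 3 (0.608, 0.966 and 0.689), or 1 and 3, 4 and 3, and 5 and 5 adjusted over the list alone. MHC genes had 1 down of 11, none, and 1 down (0.810, 0.902 and 0.702), or 2, 0 and 0 adjusted over the list alone. B-cell markers had 2 down of 10, 1 up, and 1 up and 1 down (0.150, 0.201 and 0.702), or 3 down, 1 up and 1 down adjusted over the list alone. Ighm, the heavy chain of IgM, fell by 2.46 ± 0.41 before transformation and rose by 2.33 ± 0.49 from there to the lymphomas. With the mean of its probe sets the first of these differences was -0.40 and did not pass (adjusted p = 0.252, the highest of its alternatives, the lowest being 2.19e-05), and in mice 1 and 2 alone, a setting chosen after the data were seen, the second was 2.30 and did not pass (0.0825, the highest of its alternatives, the lowest being 0.000154). Erythroid markers had 1 down of 6, 1 up, and 1 up and 2 down (0.810, 0.966 and 0.579), as adjusted over the list alone. NK and gamma-delta T-cell markers had 1 up and 1 down of 11, 2 up, and 2 up and 4 down (0.810, 0.902 and 0.702), or 1 and 2, 2 and 0, and 2 and 4 adjusted over the list alone. Of 4 measured adipose markers none changed, 1 rose and 1 fell, and 2 rose, and of 4 sex-linked genes none changed, 1 rose and 2 fell, and 1 fell. Among lists called in other comparisons, in lymphomas against mice before transformation the single-positive list had 1 up and 7 down (0.156), mitosis 2 up (0.220), DNA replication 7 up and 2 down (0.0770), Notch genes 1 up and 3 down (0.445) and interferon genes 2 up and 5 down (0.162). Adjusted over the list alone these counts differed for mitosis (1 up) and DNA replication (8 up and 2 down), and for adipose markers against control in the lymphomas (2 up and 1 down).

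Chromosome 15, which carries Myc, stood above the other autosomes in some lymphomas. The median of its 351 well-measured genes lay 0.229 above the median of the autosomes in lymphoma 5 and 0.285 above it in lymphoma 7, and it ranked first also in lymphomas 6 and 8 (0.174 and 0.112). No other autosome exceeded 0.111 in any control mouse or mouse before transformation. If an extra copy of the whole chromosome were present in lymphomas 5 and 7, both its proximal and its distal part, split at the median gene position, should be raised, and the smallest of these shifts was 0.208, above every other autosome of the same tumours (0.0482 and 0.0639). This is consistent with a gain of the chromosome in part of the cells of these tumours, as a hypothesis. In lymphoma 8 both parts also lay above the other autosomes (0.0984 and 0.114, highest other 0.0804). In lymphoma 6 the proximal part lay at 0.309 and the distal part at 0.102, within the range of its other autosomes (highest 0.117). Lymphoma 4 likewise had 0.170 in the proximal and 0.0191 in the distal part (highest other 0.0764). A gain of the whole chromosome does not cover the rise of the proximal part alone in lymphomas 4 and 6. In lymphomas 1, 2 and 3 neither part exceeded the highest other autosome.

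T-cell receptor variable segments differed between tumours. For 6 of 6 measured segments the SD over the lymphomas was larger than over either other group, for instance 1.23 for Trav12n-1 against 0.219 in controls and 0.232 before transformation. Tumours spread more in general, and 55.5% of all genes met the same condition (one-sided exact binomial p = 0.0292 for the 6 segments, taken as independent, which they may not be). That each tumour may hold few T-cell clones is 1 reading of the 6 segments and rests on few of them. Trbv13-2, Trav6-3, Trav12n-2 and Trav12n-1 lay at the floor in the lowest lymphoma. Trbv1 and Trav9d-3 stayed high in every lymphoma (11.65 to 12.80 and 11.31 to 12.76), so the reading does not cover them. In controls they lay at 13.30 to 13.36 and 12.45 to 12.63.

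Genes near Ctnnb1 passed more often before transformation than genes elsewhere. Of its 100 nearest tested neighbours 22 passed against control, where 10.5% of all genes did, and 1 of 470 overlapping windows of about that size elsewhere held as large a share. Strain-derived sequence carried along with the targeted allele is a candidate explanation, since in lymphomas against mice before transformation, which carry the same allele, 29% of the neighbours and 34.4% of all genes passed. It should also raise the share in lymphomas against controls, and there 36% of the neighbours and 40.2% of all genes passed. Of the 22 neighbours 12 (54.5%) passed in the same direction in the lymphomas, close to the 55.9% of all 1480 genes, so the explanation stays open.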
